A study of Mus musculus with 6 samples.

How the data were processed

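Whole ovaries were taken from 3 Dennd1a transgenic (TG) and 3 wild-type (WT) mice 44 h after PMSG, and total RNA was sequenced on a BGISEQ-500 instrument, per the labels' protocols. The submitters' processing notes name Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the genome build mm10, without roles or options. The annotation, the strandedness of the libraries, the mouse strain, the animals' age and any batch are not stated in the labels.

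The table deposited by the authors gives estimated counts of reads per gene and sample, per the file headers, and between 8.50% and 9.12% of the values in each library are not whole numbers, as when reads that fit several genes are divided among them. A second set of columns deposited by the authors was identified as FPKM from the values, since the headers do not name its unit. This used 322 well-counted genes with a single, long transcript, and count was divided by value and by length less a fixed number of bases. The medians gave library totals between 100.3% and 100.5% of the summed counts, and this closeness depends on the bases subtracted. The FPKM values were used in an alternative only, and the deposited group averages were not used.

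Genes were identified by Entrez number. Of the 18280 genes, 18165 matched the RefSeq gene table of assembly GRCm38.p6, which supplied coordinates, and 28 of 35 altered symbols were restored from it. Library totals ran from 17075484 to 18516171 counts, the 10 most abundant genes held between 5.57% and 5.97% of each library, and intervals from the model include the spread between animals. Reads from overlapping or antisense genes cannot be separated here.

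Counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (TMM factors between 0.990 and 1.015, filterByExpr with a minimum count of 10 and a total of 15, quasi-likelihood fit and two-sided test, Benjamini-Hochberg adjustment over 14124 genes, threshold 0.05). The common biological coefficient of variation was 12.5%. Log2 fold changes are TG over WT. A standard error is the fold change divided by the square root of the F statistic, and 95% intervals use the t distribution with the model's degrees of freedom. CPM values use the effective library sizes, except where CPM of the library total is named. Dennd1a and Fshr were also compared by an exact permutation test over 20 arrangements. The design has a single factor, the genotype, with no covariate.

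Before the data were examined, 28 gene lists were fixed. They cover FSH-responsive granulosa genes, FSH receptor signalling, steroidogenesis, cholesterol biosynthesis, LH surge, luteal cells, small-follicle granulosa, atresia, oocyte, theca, stroma, smooth muscle, endothelium, myeloid cells, lymphocytes, surface epithelium, oviduct, adipocytes, erythrocytes, skeletal muscle, S phase, G2/M phase, endocytic traffic, immediate early genes, interferon response, glycolysis, mitochondrially encoded genes and PCOS loci. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 (inter-gene correlation 0.01, log-CPM with prior count 2), adjusted over the 25 lists tested. The genes to be named were fixed by rule at the same time: Dennd1a and Fshr, up to 12 genes with the largest rise and 12 with the largest fall among those that passed, with a mean of at least 2 CPM and no overlap of the groups, and up to 4 members per list with the smallest p. Any other gene named was chosen after its values were seen, including Cyp19a1, Lhcgr, Inha, Inhba, Ccnd2, Star, Cyp11a1, Hsd3b1, Rab35, Stat2 and Crb2, and the library values of Cfd, Des and Ovgp1.

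The test was tried on simulated data, with counts for the 14124 genes drawn 10 times from the means and library sizes of these samples. Of 100 genes changed 1.5-fold per draw 46.4% were recovered and of 100 changed 2-fold 79.4%. Of the calls 9.17% were false, more than the threshold of 0.05 on the adjusted p aims at. The slope of fitted on true log2 changes was 0.996 for changed genes with a mean above 10 CPM, and genes below that mean were not assessed. The 15 FSH-responsive genes were also raised 1.5-fold in simulated TG libraries. Camera then gave that list an adjusted p of 5.92e-23, edgeR called 4 of its members and 0 other lists were called. Genes were drawn independently of each other, whereas members of a list can vary together in real libraries. The simulation therefore does not show how camera performs on these samples.

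Alternatives fixed beforehand were RLE, upper-quartile and no composition factors, no count filter or at least 50 counts in 3 samples, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) of genes with at least 1 FPKM in 3 samples, an absolute log2 fold change of at least 1, camera with an estimated correlation, and fry. Alternatives meant for a file without counts did not apply.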

Results

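RNA was sequenced from whole ovaries of mice carrying a Dennd1a transgene (TG) and of wild-type mice (WT), with 3 animals of each genotype. All 6 animals had received pregnant mare serum gonadotropin (PMSG), a hormone with FSH activity that drives follicle growth, 44 h before the ovaries were taken. DENND1A is an exchange factor for the small GTPase Rab35 and acts in endocytic traffic, and FSHR is the receptor through which granulosa cells respond to FSH. The comparison of the genotypes asks what the transgene does to the ovarian transcriptome at a time when granulosa cells are under FSH drive. Estimated counts summed to 17763323, 17593764 and 17075484 in TG replicates 1 to 3 and to 18516171, 18445260 and 17106719 in WT replicates 1 to 3, over 18280 genes. Of these genes, 14124 had enough counts to be tested, and they held at least 99.9% of the counts of every library. Replicates of a genotype differed by more than sampling noise, with a chi-square per degree of freedom between 7.92 and 21.9 for pairs of libraries, and their Spearman correlation across genes was 0.989 to 0.995. The leading principal component held 30.7% of the variance and placed the TG libraries between -20.3 and -14.0 and the WT libraries between 12.4 and 19.6.

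Dennd1a transcripts were 13-fold more abundant in TG than in WT ovaries, while the level of Fshr transcripts was close in both genotypes. Dennd1a (Entrez gene 227801) measured 570, 582 and 588 normalised counts-per-million (CPM) in TG replicates 1 to 3 and 44.6, 39.5 and 49.3 CPM in WT replicates 1 to 3. Its group means were 580.0 ± 8.97 CPM in TG and 44.5 ± 4.91 CPM in WT (SD, n = 3 each), a log2 fold change of 3.70 (SE 0.10, 95% interval 3.47 to 3.94) with an adjusted p of 4.03e-07 in edgeR. Every library therefore carried the Dennd1a level that its genotype label calls for. Fshr (Entrez gene 14309) measured 55.0 ± 6.66 CPM in TG and 50.8 ± 2.18 CPM in WT (SD, n = 3 each), and its log2 fold change was 0.12 (SE 0.10, 95% interval -0.11 to 0.34, adjusted p = 0.9997 in edgeR). In a two-sided exact permutation test of the group means p was 0.1 for Dennd1a, the smallest value that 3 animals against 3 allow, and 0.4 for Fshr.

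On the mouse assembly GRCm38, to which mm10 corresponds, Dennd1a spans positions 37798990 to 38287410 of chromosome 2 and overlaps Crb2, and Fshr spans positions 88984952 to 89200675 of chromosome 17. Crb2 had a log2 fold change of -0.21 (95% interval -1.12 to 0.69). The 17 tested genes within 1 Mb of Dennd1a, Crb2 among them, had log2 fold changes between -0.33 and 0.18, and their lowest adjusted p in edgeR was 0.9997. Gene counts do not separate transcripts of the transgene from those of the endogenous Dennd1a gene, and the labels do not describe the construct.

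**Figure D1:**
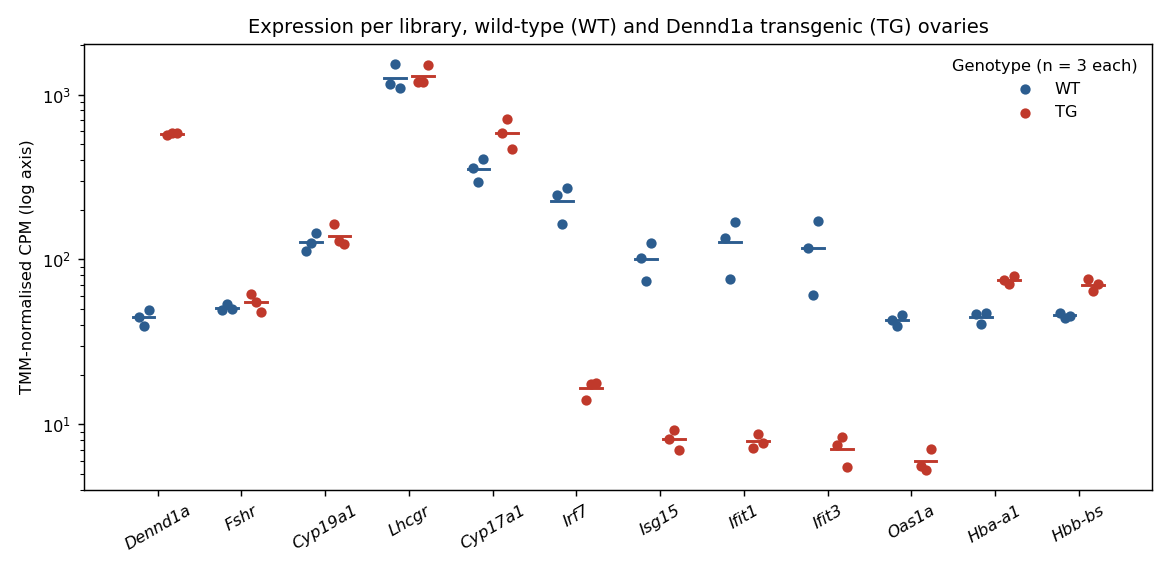
Normalised counts-per-million (CPM, log axis) of 12 genes in each of the 3 WT (blue) and 3 TG (red) libraries; points are libraries and lines are group means. Dennd1a lies at 570 CPM or more in every TG library and below 50 CPM in every WT library, Irf7, Isg15, Ifit1, Ifit3 and Oas1a are lower in every TG library than in any WT library, and the 2 groups overlap for Fshr, Cyp19a1 and Lhcgr.

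Interferon-stimulated genes were lower in TG than in WT ovaries. Throughout, fell and rose mean lower and higher in TG than in WT, the only groups compared. Ifit3, an antiviral effector, measured 7.14 ± 1.49 CPM in TG and 117 ± 55.2 CPM in WT (SD, n = 3 each), and Ifit1 fell from 127 ± 47.3 to 7.90 ± 0.824 CPM. Irf7, the transcription factor that amplifies type I interferon production, was 13.7-fold lower in TG, and the ubiquitin-like modifier Isg15 was 12.4-fold lower. In all, 149 genes changed at an adjusted p under 0.05, of which 144 were lower and 5 were higher in TG. Of the 14124 tested genes 576, these 149 among them, had an unadjusted p under 0.05 in edgeR. That is less than the share of 0.05 that would be reached without any difference. Among the 149, 118 were lower and 1, Dennd1a, was higher by a log2 fold change of at least 1. The TG and WT libraries did not overlap for any of the 149 genes, whereas 1165 of all tested genes (8.25%) had groups without overlap and chance gives 10%.

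Among genes that passed, with a mean of at least 2 CPM, the 12 largest falls were Ifit3 at a log2 fold change of -4.03 (SE 0.36), Ifit1 at -4.00 (SE 0.28), Ifit3b at -3.99, Irf7 at -3.78 (SE 0.20), Zbp1 at -3.70, Isg15 at -3.63 (SE 0.20), Slfn1, Ms4a4c and Apol9a at -3.52 each, Usp18 at -3.51, Oas1g at -3.51 and Oas3 at -3.50. Their adjusted p in edgeR lay between 2.89e-05 for Irf7 and 0.00149 for Oas3. All 12 passed in 16 of 16 alternatives, but the size of the fall depended on the scale. With limma-trend on log2(FPKM + 1) gene Oas3 had -1.51, gene Slfn1 -1.66, gene Oas1g -1.77 and gene Ms4a4c -1.99. The 1 added to each FPKM makes the log2 changes of genes with low FPKM smaller. Over the alternatives gene Oas1g reached -4.28 at the other end. Zbp1 is a sensor of Z-form nucleic acids, Usp18 removes Isg15 from its targets, and the Oas enzymes make the activator of RNase L. Counts of Ifit3, Ifit3b, Apol9a and Oas1g were not whole numbers in any of the 6 libraries, a sign of reads divided among similar genes, so the share of each within its family is uncertain. Irf7 lies on chromosome 7 (141263183 to 141266499), Isg15 on chromosome 4 (156199424 to 156200818), and Ifit1 (34640889 to 34650009) and Ifit3 (34583119 to 34588982) lie close together on chromosome 19.

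Of the interferon-response list, fixed before the data were examined, 17 of 18 members were in the data and all 17 fell in TG, both over all genes tested and adjusted over the list alone. Their median log2 fold change was -2.90 and their range -4.03 to -1.30, with Stat2 the least affected. Oas1a, whose counts were also not whole in any library, had the smallest p of the list (log2 fold change -2.84, SE 0.13, adjusted p = 1.76e-05 in edgeR), followed by Ifi44 at -3.13 (SE 0.16). The camera test placed the list lower than other genes (adjusted p = 1.10e-68), with adjusted p = 0.0759 with an estimated correlation and 0.00331 by fry, which tests whether the members move one way on balance.

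**Figure D2:**
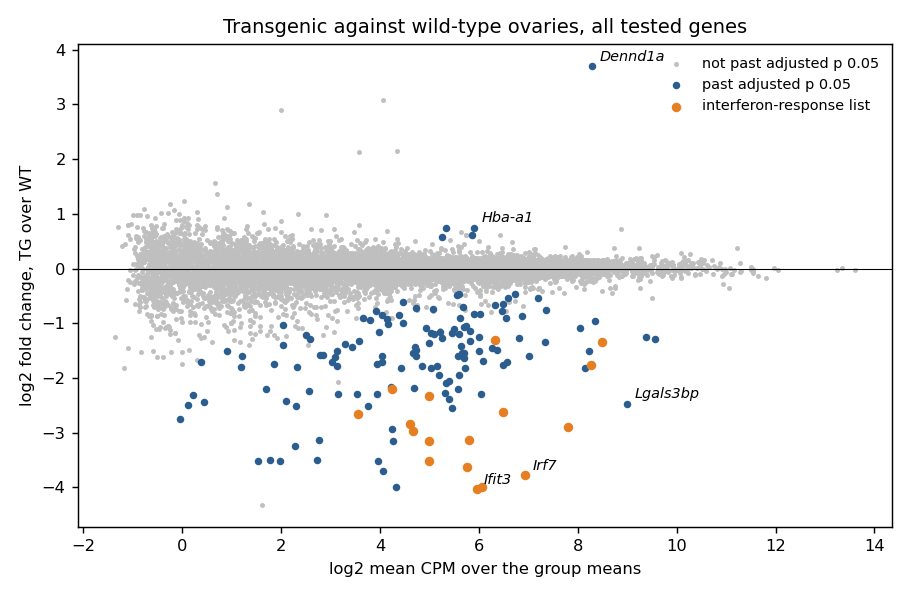
Log2 fold change of TG over WT against log2 mean CPM for the 14124 tested genes; grey points did not pass an adjusted p of 0.05, blue points did, and orange points are the 17 members of the interferon-response list. The orange points lie between -4.03 and -1.30, and Dennd1a stands at 3.70.

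Besides Dennd1a, the genes that rose in TG were the haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs and the gene a (nonagouti). Hba-a1 measured 75.4 ± 4.13 CPM in TG and 44.8 ± 3.64 CPM in WT (SD, n = 3 each), a log2 fold change of 0.75 (SE 0.09, adjusted p = 0.00214 in edgeR). Hba-a2 rose by 0.75 (SE 0.10) and Hbb-bs by 0.62 (SE 0.09) on the log2 scale. Of the 5 tested members of the erythrocyte list 3 rose over all genes tested and 4 when adjusted over the list alone, the fourth being Hbb-bt at 0.71 (SE 0.18). The camera adjusted p of this list was 1.84e-11, with adjusted p = 0.0759 with an estimated correlation. Counts of all 4 haemoglobin genes were not whole numbers in any library, a sign of reads divided among similar genes. The gene a, whose product antagonises the melanocortin receptor, lies on chromosome 2 (154950599 to 155051012) and measured 45.7 ± 3.08 CPM in TG and 30.6 ± 3.14 CPM in WT, a log2 fold change of 0.58 (SE 0.10, adjusted p = 0.0274). The call of gene a was lost without TG replicate 2, TG replicate 3, WT replicate 1 or WT replicate 2 (adjusted p between 0.0936 and 0.143) and with TG replicate 2 and WT replicate 3 both left out (0.0519), and that of gene Hbb-bs without TG replicate 3 (adjusted p = 0.0511).

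Genes that granulosa cells raise in response to FSH had levels in TG ovaries close to those in WT. Cyp19a1, the aromatase that makes oestradiol, measured 139 ± 21.9 CPM in TG and 127 ± 15.7 CPM in WT (SD, n = 3 each), a log2 fold change of 0.13 (SE 0.13, 95% interval -0.16 to 0.42). Lhcgr, the receptor for luteinising hormone, measured 1293 ± 181 CPM in TG and 1257 ± 234 CPM in WT, with a log2 fold change of 0.04 (95% interval -0.29 to 0.37). The inhibin subunit genes Inha and Inhba had log2 fold changes of 0.00 (SE 0.12) and -0.08 (SE 0.09), and the cell-cycle gene Ccnd2 had 0.05 (SE 0.09). These 5 genes were named after their values were seen. Of the 15 tested members of the list of FSH-responsive granulosa genes edgeR called 0, over all genes tested and adjusted over the list alone, and 0 had an unadjusted p under 0.05. DESeq2 and limma-voom also called 0 of them. The list median was 0.01, the members ranged from -0.31 to 0.21, and the 95% intervals of all 15 lay between -0.69 and 0.46. Members with the smallest p were Pappa at 0.21 (SE 0.11), Sgk1 at -0.31 (SE 0.17), Prkar2b at 0.15 (SE 0.09) and Fst at -0.10 (SE 0.07). The camera adjusted p was 0.742. With TG replicate 2 and WT replicate 3 both left out, the gene Sgk1 passed the test (log2 fold change -0.63, adjusted p = 0.0324).

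Components of FSH receptor signalling showed no called gene either: 0 of 23 tested members passed in edgeR, in DESeq2 and in limma-voom, and 0 had an unadjusted p under 0.05. Igf1r, Irs1, Prkar2a and Prkar1a had the smallest p, with log2 fold changes of 0.19, 0.22, -0.20 and 0.13. The median of this list was -0.02 and its mean 0.01, which differ in sign, and its camera adjusted p was 0.606. Of the 30 endocytic and trafficking genes edgeR, DESeq2 and limma-voom called 0, with 1, Dennd1c, at an unadjusted p under 0.05 in edgeR. Rab35, the GTPase that DENND1A activates, had a log2 fold change of -0.05 (SE 0.08, 95% interval -0.23 to 0.12), and its level was 78.4 ± 1.97 CPM in TG and 81.3 ± 4.26 CPM in WT. Dennd1c had -0.91 (SE 0.34) at about 1 CPM, Cltb -0.24 and Ehd4 -0.25, and the list had a median of -0.04 with a camera adjusted p of 0.0526. Of its 30 log2 fold changes 6 were above 0. The adjusted p of this list was 0.0605 by fry and 0.401 by camera with an estimated correlation.

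Among steroidogenic genes Cyp17a1, the enzyme of androgen synthesis in theca cells, measured 586 ± 120 CPM in TG and 354 ± 57.1 CPM in WT (SD, n = 3 each). Its log2 fold change was 0.73 (SE 0.16, 95% interval 0.36 to 1.09), and its adjusted p of 0.115 in edgeR did not pass over all genes, while it passed when adjusted over the list alone. The adjusted p of gene Cyp17a1 ranged from 2.48e-04 in DESeq2 to 0.342 over 16 alternatives, and it passed in DESeq2 and without TG replicate 3 (0.0382). Star measured 1756 ± 334 CPM in TG and 2144 ± 1179 CPM in WT, Cyp11a1 had a log2 fold change of -0.03 (SE 0.10) and Hsd3b1 of 0.01 (SE 0.10). In the steroidogenesis list edgeR called 0 of 18 members over all genes tested and 1, Cyp17a1, adjusted over the list alone, with 2 at an unadjusted p under 0.05. Its median was -0.01, its mean 0.03 and its camera adjusted p 0.551. The list of theca and interstitial cells, which also holds Cyp17a1, had 0 of 14 members called over all genes in edgeR, 1 adjusted over the list alone and 2 at an unadjusted p under 0.05, among them Aldh1a1 at 0.38 (SE 0.16). Its median was 0.11, and its camera adjusted p was 0.0411, with adjusted p = 0.898 with an estimated correlation. This call held in 4 of 15 alternatives and was lost with upper-quartile factors (0.0588), no composition factors (0.0560), no count filter (0.0674), the stricter filter (0.0940) and a replicate block (0.0501). In cholesterol biosynthesis 0 of 24 members passed in edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05, the median was -0.15 and the camera adjusted p 0.259. WT replicate 2 had the highest CPM of all libraries for 22 of these 24 genes. Without WT replicate 2 camera called the list higher in TG (adjusted p = 6.12e-04), and without WT replicate 1 or WT replicate 3 it called the list lower (1.86e-04 and 0.0293).

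Follicle stage and cell death lists had no called member over all genes in edgeR, in DESeq2 or in limma-voom, and none adjusted over the list alone. Genes of small-follicle granulosa cells, such as Amh at 0.18 (SE 0.12) and Igfbp5 at 0.15 (SE 0.11), had 12 of 12 log2 fold changes above 0 and 0 with an unadjusted p under 0.05. Their median was 0.11 and the camera adjusted p 0.0328, with adjusted p = 0.505 with an estimated correlation. Oocyte genes, such as Kit at 0.46 (SE 0.14), Oog1 at 0.72 (SE 0.33) and Bmp15 at 0.23 (SE 0.27), had 1 of 21 members at an unadjusted p under 0.05. Their median was 0.05 and the camera adjusted p 0.0289, with adjusted p = 0.914 with an estimated correlation. The camera call of the oocyte list was lost without TG replicate 3 (0.0821), WT replicate 1 (0.138) or WT replicate 2 (0.616). Its direction turned to lower in TG without WT replicate 2. Genes induced by the LH surge (16 tested, median 0.04, camera adjusted p = 0.551), luteal genes (11 tested, median -0.13, 0.395) and genes of atresia and apoptosis (19 tested, median -0.02, 0.606) had 0 members with an unadjusted p under 0.05. S-phase genes (22 tested, median -0.01, camera adjusted p = 0.985), G2/M genes (24 tested, median 0.01, 0.691), immediate early genes (18 tested, median -0.05, 0.691) and glycolysis and hypoxia genes (20 tested, median 0.00, mean -0.02, 0.955) likewise had 0. The camera direction was higher for the S-phase and glycolysis lists, against the sign of the S-phase median and of the glycolysis mean.

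Most markers of immune cells had log2 fold changes below 0, smaller in size than those of the interferon-response list. The leukocyte phosphatase Ptprc had a log2 fold change of -0.96 (SE 0.20, adjusted p = 0.0733), the complement gene C1qa -0.80 (SE 0.18), Laptm5 -0.65 (SE 0.15) and the receptor Csf1r, needed for macrophage survival, -0.52 (SE 0.13). In edgeR 0 of the 18 macrophage and myeloid markers passed over all genes tested, 7 were lower adjusted over the list alone and 8 had an unadjusted p under 0.05, while DESeq2 called 6 lower and limma-voom 0. The median of this list was -0.45 and its camera adjusted p 1.46e-09, with adjusted p = 0.401 with an estimated correlation. Lymphocyte markers, such as Cd4 at -0.59 (SE 0.25), had 0 of 8 called in edgeR and 1 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Their median was -0.32 and the camera adjusted p 0.0289, with adjusted p = 0.401 with an estimated correlation.

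Endothelial markers, such as Egfl7 at -0.32 (SE 0.13), Vwf at -0.58 (SE 0.24) and Pecam1 at -0.36 (SE 0.16), had 0 of 15 called in edgeR, DESeq2 and limma-voom and 2 at an unadjusted p under 0.05 in edgeR. Their median was -0.16 and the camera adjusted p 0.00833, with adjusted p = 0.885 with an estimated correlation. Stromal matrix genes (20 tested, median 0.00, mean -0.03, camera adjusted p = 0.742), smooth muscle and pericyte genes (12 tested, median -0.15, 0.606) and surface epithelium genes (13 tested, median -0.13, 0.606) had 0 members called in edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05. In the muscle list Des measured 126 CPM of the library total in WT replicate 3 and between 31.9 and 40.1 in the other libraries. Adipocyte genes (7 tested, median 0.13, mean 0.82, camera adjusted p = 0.175) had 0 called in these 3 tools and 2 at an unadjusted p under 0.05 in edgeR, and Cfd measured 85.9 CPM of the library total in TG replicate 2 against 9.41 or less elsewhere. The oviduct epithelium list had 4 tested members, of which 0 passed and 0 had an unadjusted p under 0.05 in edgeR, and its marker Ovgp1 measured 40.7 CPM of the library total in WT replicate 3 against 6.08 or less elsewhere. The skeletal muscle list had 2 tested members and the mitochondrially encoded list 0, too few for the list test.

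Loci associated with polycystic ovary syndrome (PCOS) in human genetics had 1 of 13 tested members higher in TG, Dennd1a itself, over all genes tested and adjusted over the list alone. The median of the list was 0.08 and its camera adjusted p 0.0328, with adjusted p = 0.401 with an estimated correlation. Without Dennd1a the camera adjusted p was 0.543. Of its other members, Irf1 had a log2 fold change of -0.23 (SE 0.09, adjusted p = 0.959) and Zbtb16 0.28 (SE 0.21).

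Camera called 9 of the 25 lists tested, 5 higher and 4 lower in TG. Of these, 0 hold with an estimated correlation and 3 are called by fry, namely the interferon-response, erythrocyte and PCOS lists. The PCOS list holds Dennd1a itself, and fry was not run on that list without Dennd1a. With no count filter the small-follicle, oocyte and lymphocyte lists (0.0580 each) and the PCOS list (0.117) also lost their call, and with a replicate block the PCOS list did (0.0986). In fits without 1 library the interferon-response, erythrocyte and myeloid lists were called each time, and the other 6 lost their call at least once, with adjusted p between 0.0657 and 0.692. New calls appeared for luteal (0.0121), surface epithelium (6.18e-04), smooth muscle (0.0449) and endocytic genes (0.0428) without WT replicate 3, for S-phase (0.0425) and G2/M genes (4.88e-04) without WT replicate 2, and for adipocyte genes without TG replicate 1 (0.0145) or TG replicate 3 (0.00486). With TG replicate 2 and WT replicate 3 both left out, camera called luteal (9.53e-04), surface epithelium (3.67e-04) and cholesterol biosynthesis genes (0.0254) lower and stroma (0.00728) and smooth muscle genes (0.00558) higher in TG, the endothelial list lost its call (0.145), and the luteal gene Ptgfr passed (log2 fold change -0.67, adjusted p = 0.0479). With 3 animals per genotype the exact permutation test of any single gene or list cannot give a p below 0.1.

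**Figure D3:**
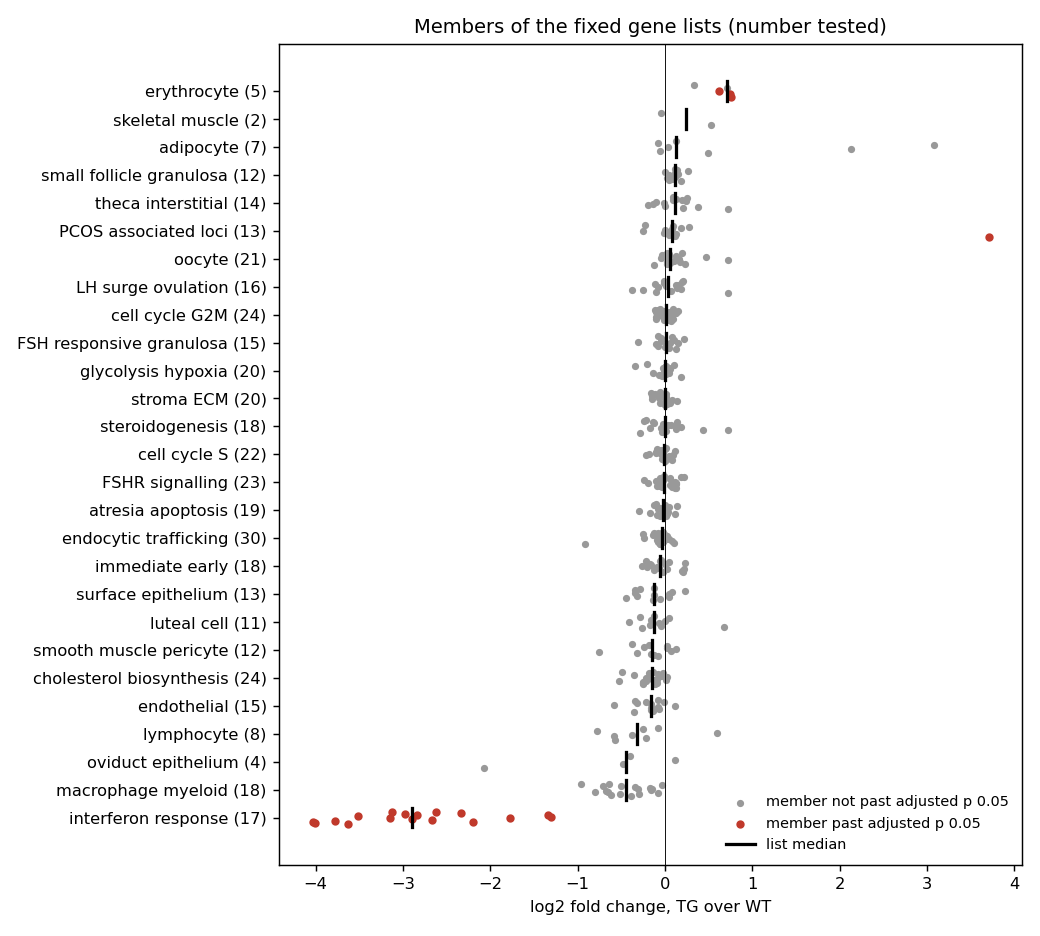
Log2 fold change of TG over WT for every tested member of the fixed gene lists, with the number tested in brackets; red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. The interferon-response list has a median of -2.90 with all 17 members red, and the FSH-responsive list has a median of 0.01 with none.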

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

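Leaving out TG replicate 2 and WT replicate 3 together, and the PCOS list without Dennd1a, were chosen after the data were seen, whereas the other alternatives were fixed before. The 149 genes called became between 119 and 202 over 16 alternatives: 149 with RLE, 148 with upper-quartile and 147 with no composition factors, 158 with no count filter, 142 with the stricter filter, 138 in limma-voom, 137 with FPKM, 202 in DESeq2 (all 149 among them), 122 (without TG replicate 3) to 178 (without WT replicate 2) without 1 library, and 119 (113 shared) without the 2 libraries. In each of these fits all 17 interferon-response genes and Dennd1a kept their direction and their call, and Fshr did not pass (log2 0.03 to 0.20). Genes higher in TG numbered 11 in DESeq2 and 1 at an absolute log2 fold change of at least 1. The number of lists called, 9, fell to 4 with no count filter, 0 with an estimated correlation and 3 with fry, and ran from 5 (without WT replicate 1) to 14 (without WT replicate 3). The interferon-response list had an adjusted p of 0.0759 with an estimated correlation, which allows for members that vary together. Uncalled lists were called in the other direction in 4 cases, and the oocyte list lost its call and changed direction in 1. Without 1 library the camera adjusted p ranged from 1.86e-04 to 0.867 for cholesterol biosynthesis, which was higher in TG at 6.12e-04 without WT replicate 2, from 3.62e-14 to 0.616 for oocyte genes, lower at 0.616 without WT replicate 2, and from 0.0449 to 0.884 for smooth muscle, higher at 0.0449 without WT replicate 3. With the 2 libraries left out, stroma (0.00728) and smooth muscle (0.00558) were called higher and luteal (9.53e-04), surface epithelium (3.67e-04) and cholesterol biosynthesis (0.0254) lower in TG, and the endothelial list lost its call (0.145). The cause of these differences was not tested. Among the other values of single genes 1799 kept their call or lack of it, 13 passed anew, 6 no longer passed and 0 changed sign with a call in either fit, and among those of lists the numbers were 314, 12, 43 and 5. Of those uncalled in both fits, 33 values of genes and 31 of lists changed sign or direction. The fit with a replicate block called 159 genes, 141 of them shared. The labels do not say whether the replicate numbers pair the animals, and the values leave this open. Same-numbered libraries had correlations of deviations of 0.23, 0.08 and 0.09, against -0.13 to 0.03 for libraries with different numbers. In all, 6 of 6 libraries correlated best with their own number, a hint from the data and not the design. The deviations were taken from the group mean, so those of a group sum to 0 and the 6 matches are not independent. They are therefore weak evidence of pairing. The replicate block gave 855 genes with an unadjusted p under 0.05 in edgeR, against 576 in the main fit. A share of 0.05 of the tested genes would lie between these counts. Alternatives that need a file without counts gave no value, nor did the erythrocyte and lymphocyte lists under the stricter filter and some single genes under that filter, DESeq2 or FPKM. Depth limits the genes that fell outside the filter and, with 3 animals each, the changes that can be found: of simulated changes 46.4% were recovered at 1.5-fold and 79.4% at 2-fold. Of the simulated calls 9.17% were false, above the share of 0.05 that the threshold aims at.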

Other observations

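The gene families, single genes and library values below, and the tests on myeloid markers, single libraries, label fields, Alas2 and fat markers, were chosen after the results were seen, whereas the counts over other splits of the samples were planned.

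The fall in TG ovaries reached across families of interferon-inducible genes, while no tested gene of the interferon receptors and their kinases passed. All 7 tested immunity-related GTPases, which attack the vacuoles of intracellular pathogens, were lower in TG with a median log2 fold change of -1.95, and so were 7 of 9 guanylate-binding proteins (median -1.20), 8 of 11 HIN-200 proteins (median -1.60), 5 of 8 Schlafen proteins (median -1.12), 6 of 10 oligoadenylate synthetases (median -2.75) and 4 of 6 Ifit genes (median -3.09). Among the synthetases Oas1e at 0.10, Oas1d at 0.02, Oas1h at 0.09 and Oas1c at -0.43 did not pass. Of the MHC class I heavy chains, which display peptides to CD8 T cells, 7 of 13 were lower, with H2-K1 at -0.97 and H2-D1 at -1.09, and reads of these similar genes are hard to assign. Of 8 genes that load class I molecules 6 were lower, among them B2m, which fell from 1076 ± 74.2 to 442 ± 43.7 CPM (SD, n = 3 each). MHC class II genes and their regulators had 0 of 7 called and a median of -0.16, and the interferon receptors and their kinases, Ifnar1 and Jak1 among them, had 0 of 7 called, a median of -0.04 and a range of -0.14 to 0.07. In both of these groups 0 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 and limma-voom called 0. The chemokine gene Cxcl10 fell by 1.71 on the log2 scale, and Cxcl9 had -1.08 with an adjusted p of 0.9997.

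Genes outside the fixed lists also passed, and those named here were picked by hand and form no tested group. Siglec1, a sialic acid receptor, fell by 1.59 on the log2 scale, the Fc receptor gene Fcgr1 by 1.79, the protease gene Ctss by 0.91, Mpeg1 by 0.82 and Cybb by 0.77. Away from immune genes, the neighbouring genes Hinfp (chromosome 9, 44292438 to 44305716) and C2cd2l (44309237 to 44320282) fell by 0.95 (SE 0.12) and 1.02 (SE 0.11) on the log2 scale. C2cd2l measured 11.9 ± 0.909 CPM in TG and 24.1 ± 1.72 CPM in WT (SD, n = 3 each), and both genes were called in 16 of 16 alternatives, with adjusted p between 1.50e-09 and 0.0282 for C2cd2l and between 5.89e-07 and 0.0377 for Hinfp. The labels do not give the insertion site of the transgene, and whether the fall of these neighbours comes from an insertion there was not tested. The 144 genes lower in TG lay on 19 chromosomes, with at most 21 on any of them. WT replicate 2 stood apart in sterol genes: it had the highest CPM for 22 of 24 cholesterol biosynthesis genes, with Fdps at 1304 CPM against 404 to 781 in the other 5 libraries, and Star measured 3463 CPM against 1193 to 1976.

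The real split of the 6 samples into 3 and 3 called 149 genes and the highest of the other splits 0. Thus 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. Every other split also mixes the genotypes, so genotype differences add to the spread within its groups and make calls of those genes unlikely. For gene lists the real split called 9 and the highest other split 14, and 5 of the 10 splits called at least 9. That split with 14 set TG replicates 1 and 2 and WT replicate 3 against the rest, so list calls by camera here also follow structure among the samples other than genotype.

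The lower level of interferon-response genes in TG than in WT is the pattern that most calls for follow-up. With no reference besides TG and WT, a fall in TG cannot be told apart from a rise in WT. The mean log-CPM of the list had an SD of 0.029 over the TG libraries and 0.356 over the WT libraries. Fewer myeloid cells in TG ovaries would lower myeloid markers about as much. The 14 markers of the fixed list outside MHC class II had a median log2 change of -0.57 and none below -0.96. The upper quartile of the interferon-response genes was -2.33, which argues against a general loss of myeloid cells as the whole cause and leaves a part open. Among the genes picked by hand above, Siglec1 (-1.59) and Fcgr1 (-1.79) fell more than any of these markers. Ctss (-0.91), Mpeg1 (-0.82) and Cybb (-0.77) fell more than the marker median but not beyond the lowest marker. Other leukocyte genes, also picked by hand, passed and fell further than any of the markers, among them Ly6c2 (-3.25), Ms4a6b (-1.58) and Fcgr4 (-1.57). Whether such genes fell with the interferon response or with a cell subset cannot be told from these values. A loss of a single myeloid subset was not tested. An aberrant library is also argued against, since at least 17 of 17 members were lower in every fit without 1 library. A difference in housing, exposure or processing batch between the genotype groups cannot be told apart from the genotype, since 0 label fields give a cage, litter, batch, date or strain. An effect of the Dennd1a transgene therefore stays open as a hypothesis beside a difference in infection or housing, and animals of both genotypes from shared litters and cages could separate them.

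The rise of haemoglobin genes in TG may reflect more residual blood in the TG ovaries. The erythroid enzyme gene Alas2 had a log2 change of 0.33 (95% interval -0.18 to 0.84), an interval that includes both 0 and the lowest haemoglobin change of 0.62, so it decides nothing. Blood content and a change with genotype cannot be told apart from these values.

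Transcripts of fat, oviduct and muscle were high in single libraries, and a candidate explanation is other tissue carried into a library at dissection. In TG replicate 2 all 6 fat markers (Adipoq, Cfd, Retn, Cidec, Fabp4 and Lep) exceeded every other library, by 4.13-fold to 9.16-fold. WT replicate 3 was next for Adipoq, Cfd, Retn, Cidec and Lep, and it had the most Ovgp1, Des, Cnn1 (81.9 CPM of the library total) and Actg2 (178 CPM). Fabp4 was also found at 3.51 to 5.80 CPM in the other libraries, whereas Adipoq stayed at 1.52 CPM or less there, and no biological explanation was tested.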
